A study of Mus musculus with 23 samples.

How the data were processed

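Bulk RNA-seq was done on brain tissue from C57BL/6J mice that were wild type (WT) or carried Csf1R-G793A, a substitution in the colony-stimulating factor 1 receptor. The mice ate control chow or chow with PLX3397 (290 mg/kg) or PLX5622 (1200 mg/kg) for 14 days. Per the labels, RNA was extracted with the RNeasy mini kit, stranded mRNA libraries were made with oligo-dT selection, and sequencing was on a NovaSeq instrument. The labels give no brain region, sequencing batch or sex. The 23 libraries make 6 groups, with 3 WT control libraries and 4 libraries in each other group. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples.

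The authors' processing notes name FastQC 0.11.9, kallisto 0.46.1, DESeq2 1.26.0 and the mouse build GRCm39, and the step from transcripts to genes is not given in the sources used here. The deposited count table holds expected_counts, that is, estimated counts per gene symbol that are not scaled to library size. It has 22310 named genes and 1 entry with a blank name, which was left out. Of its values, 45.3% are not whole numbers. A deposited table of the same libraries holds variance-stabilised values on a log2 scale for 15577 entries. It was used only as an alternative. Genes are identified by symbol. Positions are not given, because the annotation at hand is on another build. That annotation served only for transcript length and GC content, which were matched by symbol for 98.0% of the genes tested.

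Total counts ran from 26.3 M to 48.2 M (mega-counts) per library. Counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. TMM scaling was used, and filterByExpr (minimum count 10, minimum total count 15) left 16209 genes. One robust quasi-likelihood model held all 23 libraries with a term per group. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Each adjusted p for a gene comes from this edgeR model unless another tool is named. The common biological coefficient of variation was 0.0998. The standard error (SE) of a log2 fold change was its size divided by the root of its F statistic. Differences between the inhibitors carry 95% intervals from the same model.

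The comparisons were each group against WT controls, each G793A inhibitor group against G793A controls, and PLX5622 against PLX3397 within each genotype. An interaction term per inhibitor was the inhibitor's log2 fold change in G793A mice minus that in WT mice. Of 34 gene lists for brain cell types, immune pathways and stress responses, 33 were tested. The list of sex-linked genes was not. Lists were tested with camera on voom values (limma 3.58.1), with a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. Medians of lists are of voom log2 fold changes unless said otherwise, and adjusted p-values of lists are over the 33 lists. List scores per library are means of log2 CPM (counts-per-million) centred on WT controls. They were compared with two-sided exact permutation tests, whose smallest possible p is 0.0286 for 3 libraries against 4 and also for 4 against 4. These p-values are not adjusted for the 33 lists and 9 comparisons.

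The comparisons, the test, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names Csf1r, Csf1 and Il34 in each comparison. It adds up to 4 members past the threshold from each list, and the 5 largest changes in each direction among genes at 1 CPM or more whose groups do not overlap. Where fewer than 5 genes passed, it adds the 5 genes with the smallest p. Genes chosen in one comparison may be given in others. Some genes that the rule names are not reported here.

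Alternatives fixed in advance were RLE scaling, no filter, a filter at a mean of 1 CPM, a dispersion fit that was not robust, DESeq2 1.42.0, limma-voom, replicate number as a block, the compared groups alone, and leaving out each library in turn. Chosen after seeing the data were limma on the authors' variance-stabilised values, removal from each library of a smooth trend along transcript length and GC content, and leaving out 2 libraries with cerebellar transcripts or 4 with high Npas4. Replicate numbers do not pair libraries. The median correlation of residuals was 0.00553 over 55 same-numbered pairs of different groups and 0.0015 over 165 differently numbered pairs. No library showed Y-linked expression of the kind male tissue has, so a sex covariate was not run. Replicates of a group differed beyond counting noise, with a chi-square per degree of freedom between 6.06 and 76.3, so no library duplicates another of its group. Libraries of different groups were not compared in this way.

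The edgeR test was checked on counts simulated for all 23 libraries from each gene's mean and dispersion, independently between genes. The simulated libraries held no trend along transcript length, unlike the real ones, so too few unchanged genes may have been called. For WT mice on PLX3397 against WT controls the test recovered 62 of 100 genes changed 1.5-fold and 76 of 100 changed 2-fold. It called 8 unchanged genes in that comparison. For G793A controls against WT controls it recovered 69 and 77 of 100, with 6 unchanged genes called. Intervals and SEs cover the spread between libraries as the model estimates it.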

Results

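Gene expression was measured by RNA-seq in brain tissue of WT and Csf1R-G793A mice after 14 days on control chow, PLX3397 or PLX5622. CSF1R is the receptor kinase on which microglia and other tissue macrophages depend for survival, and both compounds inhibit it. There were 3 libraries from WT mice on control chow and 4 from each of the other groups, 23 in all. Total counts per library, in mega-counts (M), ran from 33.8 M to 39.5 M in WT controls, 30.7 M to 48.2 M in G793A controls, 33.0 M to 38.3 M in WT mice on PLX3397, 26.3 M to 43.3 M in G793A mice on PLX3397, 29.7 M to 36.2 M in WT mice on PLX5622 and 29.9 M to 40.9 M in G793A mice on PLX5622. In all, 16209 genes were tested. Values of genes are log2 fold changes ± SE from edgeR.

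Csf1r transcript stood at 93.8 ± 1.23 CPM (counts-per-million, mean ± SD, n = 3) in WT controls and at 81.4 ± 4.69 CPM (n = 4) in G793A controls. In WT mice it stood at 23.3 ± 5.12 CPM (n = 4) with PLX3397 and 12.2 ± 4.56 CPM (n = 4) with PLX5622. In G793A mice on the same diets it stood at 74.4 ± 4.24 CPM (n = 4) and 71.6 ± 8.59 CPM (n = 4). The score of 15 homeostatic microglia genes differed from WT controls by −1.98 (log2) in WT mice on PLX3397 and by −2.69 in WT mice on PLX5622 (exact permutation p = 0.0286 for each, the smallest possible). The same score differed from WT controls by −0.37 in G793A mice on PLX3397 and by −0.39 in G793A mice on PLX5622 (exact permutation p = 0.0286 for each). Against G793A controls these groups differed by −0.24 and −0.26 (exact permutation p = 0.0571 for each), and both differences use the same G793A control libraries.

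**Figure D1:**
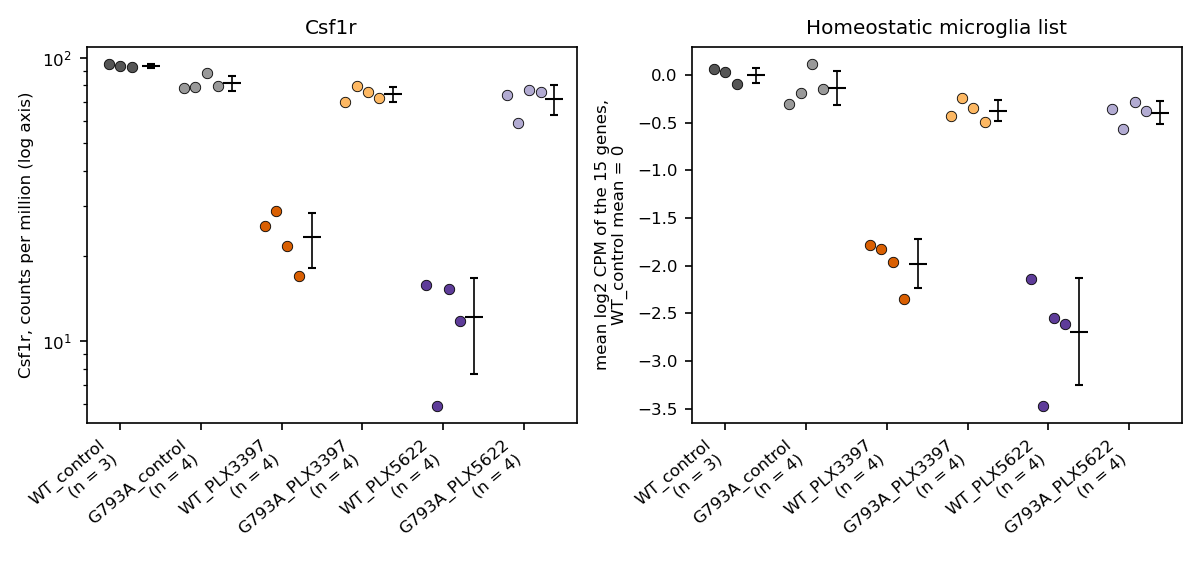
Csf1r in CPM (log axis) and the homeostatic microglia score (log2, WT control mean at 0) for each of the 23 libraries by group, with group means and SDs. WT libraries with either inhibitor lie between 5.92 and 28.9 CPM of Csf1r, and G793A libraries lie between 58.8 and 88.4 CPM.

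The comparison of WT mice on PLX3397 with WT controls (n = 4 and 3) asked what this inhibitor does to the brain transcriptome. Microglial genes fell. Csf1r fell by 2.01 ± 0.20 (adjusted p = 2.24e-06), which left 24.8% of the control level. P2ry12, a purinergic receptor of microglial processes, fell by 2.59 ± 0.19 (adjusted p = 2.42e-08), and Siglech, a microglial lectin, fell by 2.54 ± 0.18 (adjusted p = 4.05e-09). P2ry13, another purinergic receptor, fell by 2.66 ± 0.22. Across all genes 247 passed, 6 higher and 241 lower.

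Of the 15 homeostatic microglia genes 13 fell, and 15 when adjusted over the list alone (median −2.19, adjusted p = 0.000113 with an estimated correlation). Of the 16 pan-myeloid genes 15 fell, and 16 adjusted over the list alone (median −1.98, adjusted p = 0.000138 with an estimated correlation). Among them were Itgam, the integrin CD11b (−2.36 ± 0.21), Ly86 (−2.23 ± 0.22), Aif1, which encodes the marker IBA1 (−2.13 ± 0.19), and Cd53 (−1.95 ± 0.16). Border-associated macrophages line the meninges and vessels. Of their 12 genes 11 fell, and 12 adjusted over the list alone (median −2.04, adjusted p = 5.57e-08 with an estimated correlation). The mannose receptor gene Mrc1 fell by 3.93 ± 0.29 (adjusted p = 5.36e-09), and the scavenger receptor gene Stab1 fell by 2.10 ± 0.12 (adjusted p = 1.97e-10). The chemokine gene Pf4 (−3.69 ± 0.52) and the transglutaminase subunit gene F13a1 (−2.70 ± 0.33) also fell. Clec5a, a myeloid lectin receptor, fell by 2.65 ± 0.29, and Tgfb1, which encodes a cytokine that microglia make and need, fell by 1.10 ± 0.15. Ctsd, a lysosomal protease, fell by 0.31 ± 0.06. The CSF1R ligand genes Csf1 (0.01 ± 0.07) and Il34 (0.02 ± 0.08) did not pass.

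Outside the macrophage lists, 3 of 13 antigen presentation genes fell in WT mice on PLX3397, and 5 adjusted over the list alone (median −0.35, adjusted p = 0.0691 with an estimated correlation). They were the MHC class II genes H2-Aa (−1.74 ± 0.38) and H2-Ab1 (−1.30 ± 0.29) and the invariant chain Cd74 (−1.11 ± 0.25). Csf2rb, the common subunit of the GM-CSF receptor, fell by 1.18 ± 0.28. Of 5 red blood cell genes 1 fell, and 5 adjusted over the list alone (median −2.03, adjusted p = 0.0691 with an estimated correlation). It was Hba-a2 (−2.18 ± 0.53), whose reads are hard to tell from those of its near-identical copy Hba-a1. The red blood cell score differed from WT controls by −1.97 (exact permutation p = 0.0286). With the WT control mean at 0, this score was −1.11 in G793A mice on PLX3397 (−1.84 to −0.24) and −0.28 in G793A controls (−0.90 to 0.80). It was −0.54 in WT mice and −0.67 in G793A mice on PLX5622, so a low score was not particular to WT mice on PLX3397. Of 17 interferon-stimulated genes 0 fell over all genes in edgeR and 8 adjusted over the list alone (median −0.60, adjusted p = 0.117 with an estimated correlation).

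Of 12 oligodendrocyte precursor genes 1 fell with PLX3397 in WT mice, and 4 adjusted over the list alone (median −0.20, adjusted p = 0.0843 with an estimated correlation). It was the matrix gene Matn4 (−0.51 ± 0.13). Of 10 genes of committed precursors 0 fell over all genes in edgeR and 6 adjusted over the list alone, and as a group they fell (median −0.18, adjusted p = 0.0197 with an estimated correlation). Of 18 cholesterol synthesis genes 0 rose over all genes in edgeR and 3 adjusted over the list alone (median 0.13, adjusted p = 0.0843 with an estimated correlation). The genes that rose included Spink8, a peptidase inhibitor gene (1.12 ± 0.28), the phospholipase gene Pla2g4e (0.70 ± 0.17), the clock output gene Dbp (0.46 ± 0.10), the neuropeptide Y receptor gene Npy1r (0.39 ± 0.09) and the deubiquitinase gene Usp2 (0.33 ± 0.08). The 6 genes that rose had a median of 0.42 there and of 0.18 in G793A controls against WT controls, with 0 negative, a comparison that reuses the 3 WT controls. Spink8 stood at 1.45 CPM in WT controls, 2.72 CPM in G793A controls and 3.13 CPM in WT mice on PLX3397. The 12 immediate early genes all had positive values (median 0.97), and 0 passed over all genes or over the list alone (adjusted p = 0.388 with an estimated correlation). The activity-dependent gene Npas4 stood at 152 CPM in replicate 1 of this group and between 11.3 and 18.0 CPM in the other 3. Of the 33 lists 16 passed with the preset correlation and 4 with an estimated correlation.

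Of 27 genes chosen by the naming rule and past the threshold with PLX3397 in WT mice, 16 passed whichever library was left out. The other 11 all lost the call without WT control replicate 3, and some of them without each of the other 6 libraries. The highest adjusted p came without WT control replicate 3 for Spink8 (0.346), Cd74 (0.246), Pla2g4e (0.209), Csf2rb (0.201), H2-Aa (0.176), H2-Ab1 (0.163), Npy1r (0.163) and Dbp (0.109). It came without WT control replicate 1 for Usp2 (0.268) and Matn4 (0.196), and without WT PLX3397 replicate 4 for Hba-a2 (0.171).

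The comparison of WT mice on PLX5622 with WT controls (n = 4 and 3) asked the same of the other inhibitor. Csf1r fell by 2.93 ± 0.21 (adjusted p = 1.57e-08), P2ry12 fell by 3.46 ± 0.20 (adjusted p = 3.85e-10) and Siglech fell by 3.31 ± 0.19 (adjusted p = 5.11e-11). Other microglial genes that fell were P2ry13 (−3.78 ± 0.25) and the Fc receptor-like gene Fcrls (−3.60 ± 0.29). Across all genes 269 passed, 12 higher and 257 lower.

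Of the 15 homeostatic microglia genes 13 fell with PLX5622, and 15 adjusted over the list alone (median −3.01, adjusted p = 7.16e-05 with an estimated correlation). Of the 16 pan-myeloid genes 15 fell, and 16 adjusted over the list alone (median −2.59). They included Itgam (−3.22 ± 0.22), the lysosomal membrane gene Laptm5 (−2.68 ± 0.20), Tyrobp, the adaptor DAP12 that signals for TREM2 (−2.59 ± 0.20), and Cd53 (−2.55 ± 0.17). Of the 12 border-associated macrophage genes 9 fell, and 12 adjusted over the list alone (median −1.94). They included Mrc1 (−4.37 ± 0.30), Pf4 (−3.84 ± 0.54), F13a1 (−2.67 ± 0.33) and Stab1 (−2.44 ± 0.13, adjusted p = 1.41e-11). Clec5a (−3.33 ± 0.31), Tgfb1 (−1.01 ± 0.15), Csf2rb (−1.10 ± 0.28) and Ctsd (−0.34 ± 0.06) fell as well. Of 13 antigen presentation genes 3 fell, and 5 adjusted over the list alone (median −0.33, adjusted p = 0.0998 with an estimated correlation). They were H2-Ab1 (−1.27 ± 0.29), Cd74 (−1.15 ± 0.26) and the immunoproteasome gene Psmb8 (−0.86 ± 0.17).

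The largest rises in WT mice on PLX5622 were in the oligodendrocyte transcription factor gene Nkx6-2 (0.97 ± 0.22), Fam76b (0.72 ± 0.15), the kinase gene Hunk (0.65 ± 0.14), Brme1 (0.63 ± 0.16) and Dact2 (0.43 ± 0.11), among genes at 1 CPM or more whose groups did not overlap. Fam76b was at 0.68 ± 0.15 in G793A controls against the same WT controls, without an inhibitor, and did not pass there (adjusted p = 0.358). Csf1 (0.06 ± 0.07), Il34 (0.02 ± 0.08) and Pdgfra, the growth factor receptor that marks oligodendrocyte precursors (0.02 ± 0.08), did not pass. Of 12 oligodendrocyte precursor genes 0 passed in edgeR over all genes (median −0.02). Replicate 1 of this group held cerebellar transcripts (Cbln3 at 30.8 CPM) and pituitary transcripts (Prl at 66.1 CPM), and without it 278 genes passed. Of the 33 lists 7 passed with the preset correlation and 3 with an estimated correlation.

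Of 26 genes chosen by the naming rule and past the threshold with PLX5622 in WT mice, 18 passed whichever library was left out. Of the other 8, all but Fam76b lost the call without WT control replicate 3, and some without each of the other 6 libraries. The highest adjusted p came without WT control replicate 3 for Brme1 (0.306), Dact2 (0.284), Csf2rb (0.27), H2-Ab1 (0.177), Cd74 (0.176), Nkx6-2 (0.173) and Hunk (0.102), and without WT control replicate 1 for Fam76b (0.0654).

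The genes that fell with the inhibitors in WT mice overlapped in 206, which is 85.5% of those with PLX3397 and 80.2% of those with PLX5622. Both comparisons use the same 3 control libraries. In 30 simulations with those shared controls and no inhibitor effect the overlap was 0, and independent lists of these sizes would share 3.82 genes. The simulations leave out the inhibitor effects and the independent lists leave out the shared controls, so part of the excess over either may come from the shared controls. Only 1 gene rose with both inhibitors, 0.00444 would do so in independent lists, and 0 went in opposite directions. Over all genes the log2 fold changes of the inhibitors had a Pearson r of 0.735 across genes, which are not independent replicates, against a mean of 0.572 (0.504 to 0.677) in the simulations. The covariance was 0.102 against 0.0418 simulated, a difference of 0.0603. The simulations also held no trend along transcript length. Such a trend in the shared controls could raise both values, so the simulated ones may be too low. The 3 controls are too few to be divided between the comparisons.

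PLX5622 and PLX3397 were compared within WT mice (n = 4 and 4), at chow doses that differ (1200 and 290 mg/kg), so the values stand side by side without a matched dose. Csf1r was at −0.92 with PLX5622 relative to PLX3397 (95% interval −1.34 to −0.51), P2ry12 at −0.87 (−1.30 to −0.44), Siglech at −0.76 (−1.18 to −0.34), the fractalkine receptor gene Cx3cr1 at −1.10 (−1.54 to −0.67) and Stab1 at −0.33 (−0.60 to −0.07). Pdgfra was at 0.32 (0.16 to 0.48), and Mrc1 at −0.44 (−1.25 to 0.37). None of these passed over all genes. Of 15 homeostatic microglia genes 0 passed over all genes and 10 were lower adjusted over the list alone (median −0.80, adjusted p = 0.0804 with an estimated correlation). Of 16 pan-myeloid genes 0 passed over all genes and 9 were lower adjusted over the list alone (median −0.68, adjusted p = 0.107 with an estimated correlation). Of 12 oligodendrocyte precursor genes 0 passed over all genes and 4 were higher adjusted over the list alone (median 0.18, adjusted p = 0.0804 with an estimated correlation), and of 5 red blood cell genes the numbers were 0 and 5 (median 1.41, adjusted p = 0.0804 with an estimated correlation).

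In that comparison of inhibitors in WT mice edgeR called 0 genes, with 664 at an unadjusted p under 0.05, fewer than the 810 expected by chance in each comparison, while DESeq2 called 14 and limma-voom 0. The smallest edgeR p-values belonged to Lag3, an immune checkpoint gene that microglia express (−1.29 ± 0.22, adjusted p = 0.0627), the pseudogenes Lamtor3-ps (−4.35) and Gm6710 (−0.42), which are uncertain because they share sequence with other genes, Cx3cr1 (−1.10 ± 0.21) and the checkpoint gene Vsir (−0.49), and none passed. Without WT PLX5622 replicate 1 the count was 7, and without replicate 3 it was 2.

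G793A controls were compared with WT controls (n = 4 and 3) for the effect of the substitution without an inhibitor. Csf1r (−0.20 ± 0.19, adjusted p = 0.729), Csf1 (−0.05) and Il34 (0.06) did not pass. Csf1r lay between 78.5 and 88.4 CPM in G793A controls and between 92.8 and 95.1 CPM in WT controls, without overlap. Its SE also takes in the spread of WT mice on the inhibitors, so Csf1r is not shown to be unchanged by the substitution. The smallest p-values belonged to Fam76b (0.68 ± 0.15), Arhgdig (0.36) and the zinc finger genes Zfp995 (0.57), Zfp771 (0.46) and Zfp536 (−0.36), each with an adjusted p of 0.358. The homeostatic microglia genes had a median of −0.16 and 0 of 15 passed over all genes or over the list alone (adjusted p = 0.0809 with the preset correlation and 0.994 with an estimated correlation). The border-associated macrophage genes had a median of −0.37, with 0 of 12 past the threshold either way (adjusted p = 0.178 with an estimated correlation, 0.0164 with the preset one and 0.0232 in fry). Their score differed by −0.30 (exact permutation p = 0.0571).

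In G793A controls against WT controls edgeR called 0 genes, with 1803 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Without G793A control replicate 2 edgeR called 375. Of those, 191 were higher and had a median transcript length of 734 bases, 184 were lower with a median of 4732 bases, and the median of all genes tested was 2256 bases.

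G793A mice on PLX3397 were compared with WT controls (n = 4 and 3) to ask whether the substitution prevents the inhibitor's effects, and with G793A controls (n = 4 and 4). Pdgfra fell by 0.54 ± 0.08 against WT controls (adjusted p = 0.0154), and it was the only gene past the threshold. It also fell by 0.54 ± 0.08 against G793A controls (adjusted p = 0.00678), again alone. Csf1r did not pass against WT controls (−0.33 ± 0.19, adjusted p = 0.756) or against G793A controls (−0.13 ± 0.18). Siglech (−0.60 ± 0.16 and −0.40 ± 0.15) and P2ry12 (−0.55 ± 0.17 and −0.32 ± 0.16) did not pass against either. The model shares a spread per gene over all 6 groups, so these SEs also take in the spread of WT mice on the inhibitors. Csf1r lay between 69.9 and 79.7 CPM in this group and between 92.8 and 95.1 CPM in WT controls, without overlap. G793A controls, which were given no inhibitor, lay between 78.5 and 88.4 CPM. They too were below the WT controls, and their range overlapped that of G793A mice on PLX3397. With SEs that take in this wider spread, a microglial gene that did not pass in G793A mice on either inhibitor is not shown to be unchanged. The next smallest p-values against WT controls belonged to the cyclin gene Ccnd1 (−0.43, adjusted p = 0.0564), Stab1 (−0.60, 0.117), Rasgrp3 (−0.46, 0.124) and the endothelial gene Plvap (0.49). Against G793A controls they belonged to Matn4 (−0.62 ± 0.12, adjusted p = 0.169), Ccnd1 (−0.34), Foxred2 (0.29) and Pcdha12 (0.33), which shares sequence with its gene cluster and is uncertain.

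Border-associated macrophage genes were lower as a group in G793A mice on PLX3397 than in WT controls (median −0.73, adjusted p = 0.000109 with an estimated correlation), with 0 of 12 past the threshold over all genes in edgeR and 5 adjusted over the list alone. Against G793A controls the median was −0.33 (adjusted p = 0.0719 with an estimated correlation, 0.0116 in fry). All 15 homeostatic microglia genes had negative values against WT controls (median −0.35, 0 past the threshold over all genes and 2 adjusted over the list alone, adjusted p = 0.134 with an estimated correlation). Against G793A controls all 15 were again negative (median −0.21, adjusted p = 0.414 with an estimated correlation). Of 12 oligodendrocyte precursor genes 1 fell against G793A controls, and 6 adjusted over the list alone (median −0.17, adjusted p = 0.182 with an estimated correlation, 0.0293 in fry). The precursor score differed by −0.24 (exact permutation p = 0.0286). Of 12 glucocorticoid-induced genes 0 passed over all genes and 8 were higher adjusted over the list alone (median 0.41, adjusted p = 0.236 with an estimated correlation). Of 12 immediate early genes 0 passed against WT controls over all genes and 7 were higher adjusted over the list alone (median 1.23, adjusted p = 0.211 with an estimated correlation). Npas4 stood at 185 and 214 CPM in replicates 2 and 4 of this group and at 8.04 and 16.2 CPM in the others.

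At an unadjusted p under 0.05 edgeR counted 1173 genes for G793A mice on PLX3397 against WT controls and 1899 against G793A controls. DESeq2 called 26 and 28, limma-voom 3 and 1, and edgeR fitted to only the groups compared 0 and 0. Against WT controls Pdgfra lost its call without WT control replicate 2 (adjusted p = 0.145) or replicate 3 (0.13), which left 0 genes, and the count was 2 without G793A PLX3397 replicate 1 and 4 without its replicate 3. Against G793A controls the call was lost without G793A control replicate 4 (adjusted p = 0.0535), which left 0, and the count was 23 without G793A control replicate 2 and 2 without G793A PLX3397 replicate 1, 2 or 3.

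G793A mice on PLX5622 were compared in the same way with WT controls (n = 4 and 3) and with G793A controls (n = 4 and 4). Csf1r did not pass against WT controls (−0.39 ± 0.19, adjusted p = 0.748) or G793A controls (−0.18 ± 0.18). Pdgfra was at −0.02 ± 0.08 and −0.01 ± 0.08, Siglech at −0.61 ± 0.16 and −0.41 ± 0.15, and Stab1 at −0.67 ± 0.12 and −0.37 ± 0.11, and none of them passed. The smallest p-values against WT controls belonged to Stab1 (adjusted p = 0.118), Fam76b (0.75), the inositol kinase gene Ipmk (−0.24), Nfam1, an immune receptor gene (−0.86), and Scamp2 (−0.27). Against G793A controls they belonged to the transglutaminase gene Tgm2 (−0.50), the histone deacetylase gene Hdac5 (−0.32), Adam23 (0.28), Jmy (0.22) and the sialyltransferase gene St8sia1 (0.35), each with an adjusted p of 0.147.

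Border-associated macrophage genes were lower as a group in G793A mice on PLX5622 than in WT controls (median −0.57, adjusted p = 0.0011 with an estimated correlation), with 0 of 12 past the threshold over all genes in edgeR and 1 adjusted over the list alone. Against G793A controls the median was −0.24 (adjusted p = 0.848 with an estimated correlation, 0.331 in fry). Their score, with the WT control mean at 0, was −0.30 in G793A controls and −0.52 in G793A mice on PLX5622 (difference −0.22, exact permutation p = 0.0571). The 15 homeostatic microglia genes were all negative against WT controls (median −0.40, 0 past the threshold over all genes and 2 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation) and against G793A controls (median −0.24, adjusted p = 0.848 with an estimated correlation). Of 8 blood leukocyte genes 0 passed against WT controls over all genes and 4 were higher adjusted over the list alone (median 1.65, adjusted p = 0.169 with an estimated correlation). Choroid plexus genes had a median of −0.58 (adjusted p = 0.543 with an estimated correlation). Cerebellar neuron genes had a median of 0.59 (adjusted p = 0.737 with an estimated correlation). Replicate 2 of this group held cerebellar transcripts, with Cbln3 at 221 CPM and Gabra6 at 78.4 CPM.

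For G793A mice on PLX5622 edgeR called 0 genes against WT controls (1095 at an unadjusted p under 0.05, 8 in DESeq2, 1 in limma-voom) and 1 without WT control replicate 1. Against G793A controls it called 0 (2639 at an unadjusted p under 0.05, 313 in DESeq2, 0 in limma-voom) and 980 without G793A control replicate 2. Of those 980, 542 were higher with a median transcript length of 4327 bases, and 438 were lower with a median of 904 bases.

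The interaction terms tested whether an inhibitor's effect differed between the genotypes (n = 4, 4, 4 and 3 libraries). A positive value means a smaller fall, or a larger rise, in G793A mice. For PLX3397 the interaction was 1.88 ± 0.27 for Csf1r (adjusted p = 0.000803), 2.14 ± 0.24 for Siglech (1.62e-05), 2.26 ± 0.25 for P2ry12, 2.05 for Itgam, 1.95 for the Fc receptor subunit Fcer1g, 1.79 for Aif1 and 1.71 for Cd53. Among border-associated macrophage genes it was 3.39 ± 0.37 for Mrc1, 1.80 ± 0.17 for Stab1 (2.03e-06) and 1.95 for F13a1. The lectin gene Cd209f, with counts near the floor in WT mice on the inhibitor (0.0285 CPM), also passed (adjusted p = 0.0302). The interaction was 2.89 for Pf4, 2.64 for the ficolin gene Fcna and 1.14 for Tgfb1. In all 90 genes passed, 89 of them positive, and the exception was Npbwr1, a neuropeptide receptor gene (−0.94, adjusted p = 0.0387). Of 15 homeostatic microglia genes 13 passed (median 1.93, 14 adjusted over the list alone), as did 14 of 16 pan-myeloid genes (median 1.74, 15 adjusted over the list alone) and 5 of 12 border-associated macrophage genes (median 1.83, 12 adjusted over the list alone). The microglia list had an adjusted p of 9.83e-05 with an estimated correlation.

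For PLX5622 the interaction was 2.75 ± 0.27 for Csf1r (adjusted p = 5.46e-06), 3.32 ± 0.26 for P2ry12, 2.89 ± 0.25 for Siglech, 3.04 for Itgam and 2.41 for Cd53. It was 4.00 ± 0.38 for Mrc1, 2.07 ± 0.17 for Stab1, 3.33 for Pf4 and 0.93 for Tgfb1. Cd209f, with counts near the floor in WT mice on the inhibitor, also passed (adjusted p = 0.00755). In all 131 genes passed, 130 of them positive, and the exception was Plcxd1 (−0.75, adjusted p = 0.0155). The homeostatic microglia genes (13 of 15, and 13 adjusted over the list alone) had a median of 2.82 (adjusted p = 0.000263 with an estimated correlation). The pan-myeloid genes (15 of 16, and 16 adjusted over the list alone) had a median of 2.39, and the border-associated macrophage genes (5 of 12, and 11 adjusted over the list alone) a median of 1.91.

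Of 17 genes chosen by the naming rule and past the threshold for the PLX3397 interaction, 5 lost the call without at least 1 library, and each did so without most of the libraries in turn. The highest adjusted p was 0.16 for Npbwr1 without WT control replicate 3, 0.154 for Fcna and 0.095 for Cd209f without WT control replicate 2, and 0.135 for Pf4 and 0.0844 for F13a1 without WT control replicate 1. For the PLX5622 interaction 1 of 16 lost it, Plcxd1, without WT control replicate 1 or 2 (adjusted p = 0.0808 without replicate 2).

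The 241 genes that fell with PLX3397 in WT mice had a median of −1.31 there and of −0.21 in G793A mice on PLX3397 against G793A controls, where 90.5% were negative (camera p = 0.0265 with an estimated correlation, fry p = 0.0109, neither adjusted). In G793A mice on PLX5622 against G793A controls they had a median of −0.18, with 88.4% negative (camera p = 0.0628 with an estimated correlation, fry p = 0.0195). In G793A controls against WT controls the median was −0.10 (0.208 and 0.113). These genes were chosen on the WT libraries. The comparisons of G793A mice on an inhibitor with G793A controls do not reuse those libraries. They share the same G793A controls, however, so high values there would lower both medians, and they are not independent of each other. The comparison of G793A controls with WT controls reuses the 3 WT controls, which can draw its median below 0. The 257 genes that fell with PLX5622 in WT mice had a median of −0.17 in G793A mice on PLX5622 against G793A controls, with 86.4% negative (camera p = 0.0835 with an estimated correlation, fry p = 0.0301).

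**Figure D2:**
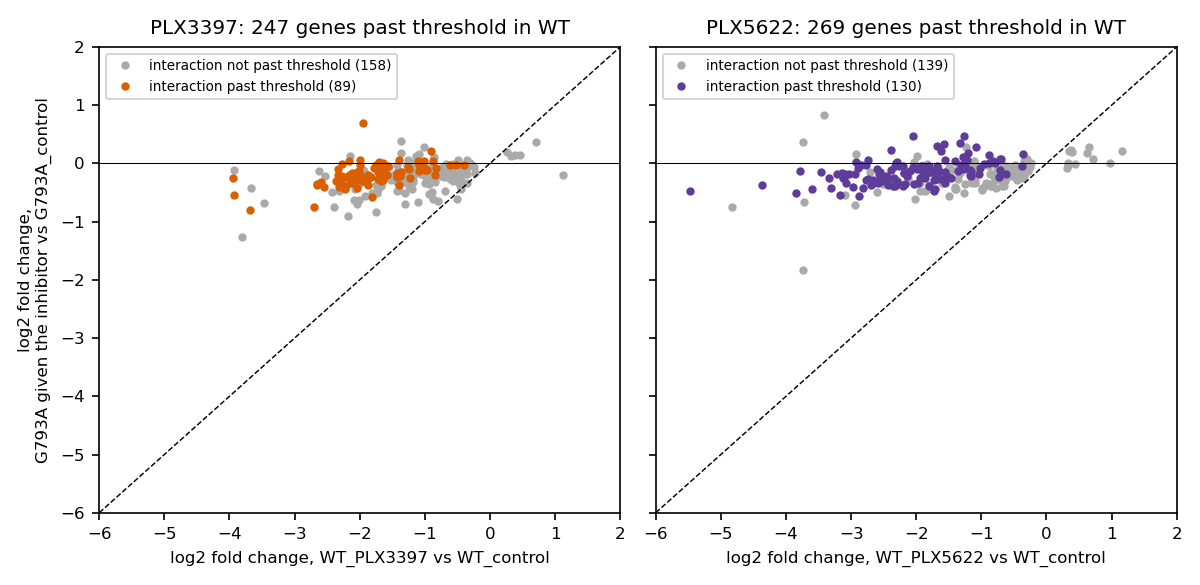
Log2 fold change in WT mice against that in G793A mice, each against the controls of its own genotype, for the 247 genes past the threshold with PLX3397 (left) and the 269 with PLX5622 (right), coloured by whether the interaction passed. In WT mice most points lie below 0, and in G793A mice they lie close to 0, with 89 and 130 past the interaction threshold.

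PLX5622 and PLX3397 were also compared within G793A mice (n = 4 and 4, doses 1200 and 290 mg/kg). Pdgfra was higher with PLX5622, by 0.53 ± 0.08 (95% interval 0.37 to 0.69, adjusted p = 0.00899), and it was the only gene past the threshold. Csf1r was at −0.06 (−0.43 to 0.32), P2ry12 at 0.18 (−0.17 to 0.52), and neither passed. The next smallest p-values belonged to Pkmyt1, a cell cycle kinase gene (−0.47), Npbwr1 (0.63), the T cell gene Cd28 (1.52) and the pseudogene Gm6802 (−2.14, uncertain because it shares sequence with other genes), each with an adjusted p of 0.657. Oligodendrocyte precursor genes had a median of 0.16, with 1 of 12 higher over all genes and 2 adjusted over the list alone (adjusted p = 0.197 with an estimated correlation). Glucocorticoid-induced genes had a median of −0.46, with 0 of 12 past the threshold over all genes and 9 lower adjusted over the list alone (adjusted p = 0.197 with an estimated correlation).

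Pdgfra stood at 66.7 ± 2.97 CPM (mean ± SD, n = 3) in WT controls, 66.3 ± 2.83 CPM (n = 4) in G793A controls, 54.1 ± 3.18 CPM (n = 4) in WT mice on PLX3397 and 45.7 ± 6.66 CPM (n = 4) in G793A mice on PLX3397. With PLX5622 it stood at 67.7 ± 0.824 CPM (n = 4) in WT mice and 65.9 ± 5.59 CPM (n = 4) in G793A mice. In WT mice on PLX3397 it did not pass against WT controls (−0.30 ± 0.08, adjusted p = 0.0716). The PLX3397 interaction of Pdgfra was −0.23 ± 0.11 and did not pass. In the comparison of inhibitors in G793A mice edgeR counted 1110 genes at an unadjusted p under 0.05 and DESeq2 called 2, and the Pdgfra call was lost without G793A PLX5622 replicate 3 (adjusted p = 0.0833) or replicate 4 (0.0856), which left 0 genes.

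**Figure D3:**
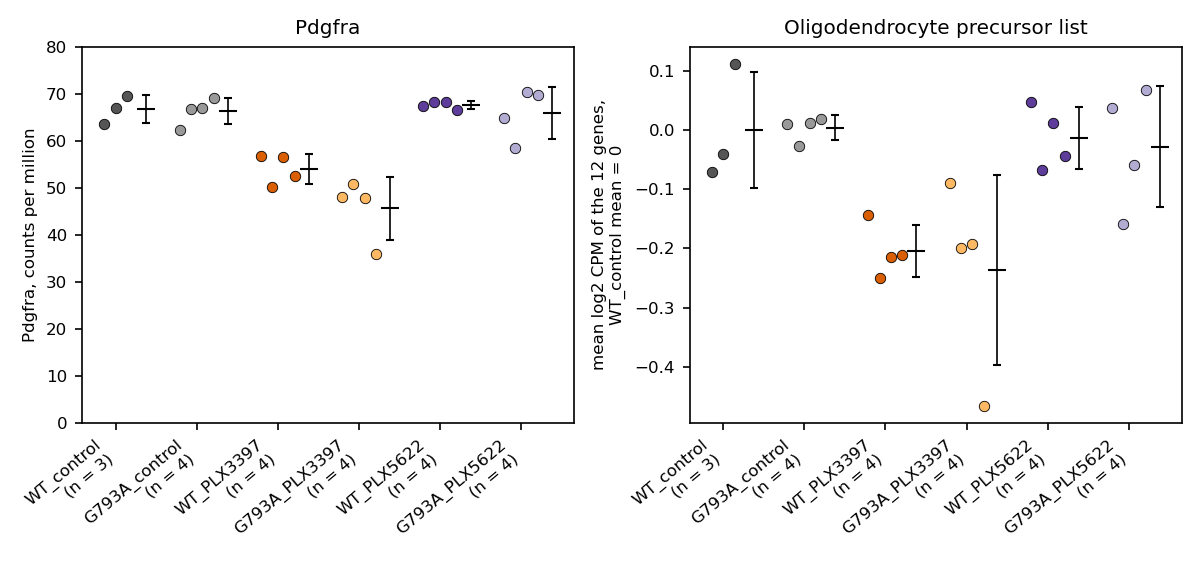
Pdgfra in CPM and the oligodendrocyte precursor score (log2, WT control mean at 0) for each library by group, with group means and SDs. The 4 G793A libraries on PLX3397 lie between 35.9 and 50.7 CPM of Pdgfra, below the G793A libraries on the other diets.

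**Figure D4:**
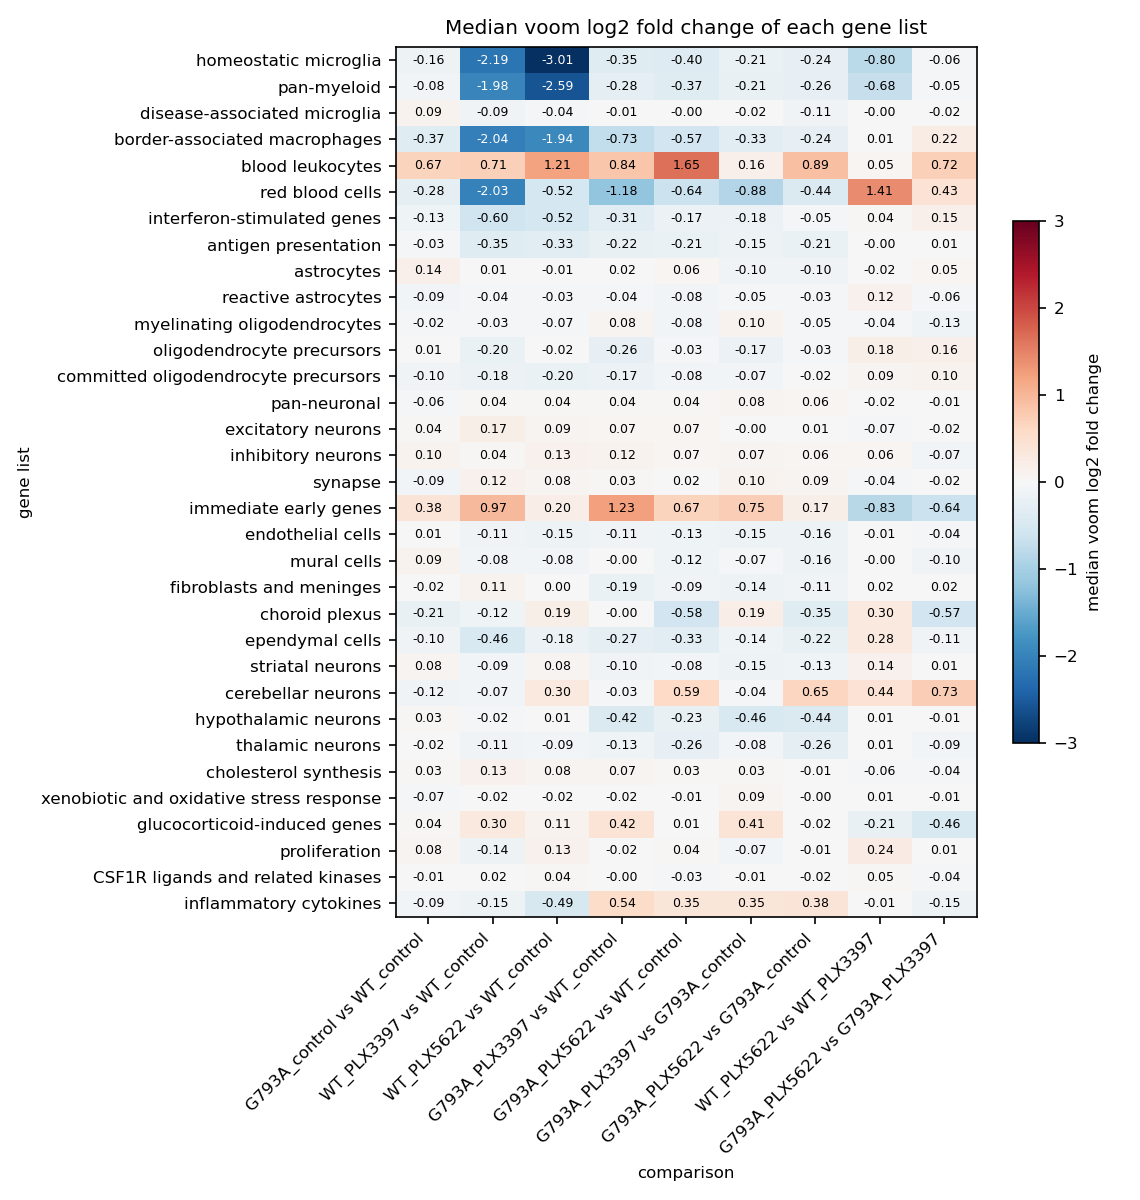
Heat map of the median voom log2 fold change of 33 gene lists in 9 comparisons. The homeostatic microglia list reads −2.19 and −3.01 in WT mice on PLX3397 and PLX5622, and −0.35 and −0.40 in G793A mice on them, each against WT controls.

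Libraries differed along transcript length, and the groups followed this in part. Over 10436 genes the Spearman correlation across genes between transcript length and a library's deviation from the mean was −0.256, 0.299 and 0.254 in the WT controls and −0.359, 0.180, −0.430 and −0.297 in the G793A controls. It lay between 0.233 and 0.282 in WT mice on PLX3397 and between −0.301 and 0.0926 in G793A mice on PLX3397, without overlap. With PLX5622 it lay between −0.0268 and 0.283 in WT mice and between −0.0813 and 0.255 in G793A mice. With this trend removed, a choice made after seeing the data, 253 genes passed with PLX3397 and 265 with PLX5622 in WT mice. Mitochondrial genes took 7.10% of counts in G793A control replicate 3, the highest share of any library.

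**Figure D5:**
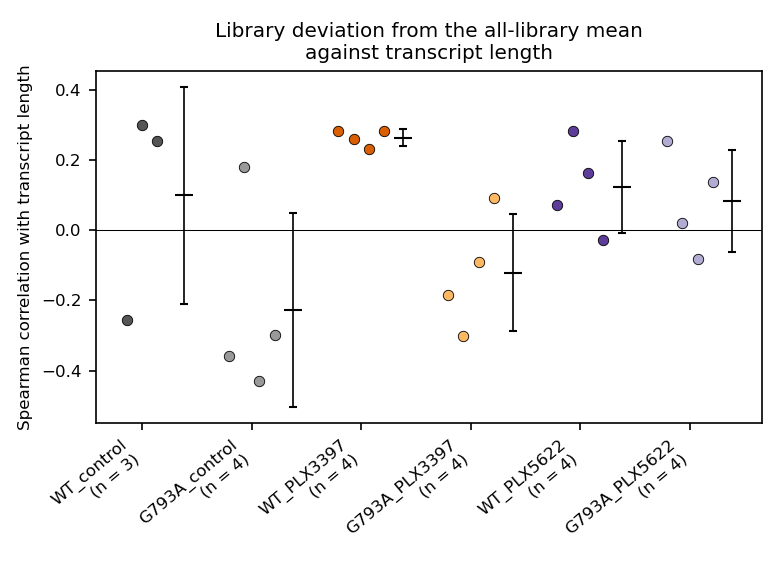
Spearman correlation across genes between transcript length and each library's deviation from the mean, per library and group. Replicate 2 of the G793A controls, at 0.180, stands apart from the other 3 of its group.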

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

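Tests chosen after the result was seen were the splits with the length and GC trend removed, the comparison of Pdgfra between the inhibitors, the myelinating oligodendrocyte list, and the splits of the 12 G793A libraries. Of 195 groups of 4 libraries checked for a library far from the rest, 11 were picked out, and chance alone picks out about 10 (about 1 in 20).

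Scores here are log2 with the WT control mean at 0. The pan-myeloid score was −0.16 in G793A PLX3397 replicate 2, far from the others of its group (−0.34 to −0.31). The border-associated macrophage score was −2.26 in WT PLX3397 replicate 4 (others −2.05 to −2.03) and −1.69 in WT PLX5622 replicate 1 (others −2.19 to −2.12). In WT PLX5622 replicate 1 the myelinating oligodendrocyte score was 0.23 (others −0.20 to −0.13) and the cerebellar neuron score 2.00 (others −0.07 to −0.00). The cerebellar neuron score was 3.82 in G793A PLX5622 replicate 2 (others −0.22 to −0.11). The immediate early gene score was 2.01 in WT PLX3397 replicate 1 (others 0.55 to 0.69), and the striatal neuron score 0.22 in WT PLX5622 replicate 3 (others 0.01 to 0.02). Csf1r stood at 88.4 CPM in G793A control replicate 3 (others 78.5 to 79.8) and at 58.8 CPM in G793A PLX5622 replicate 2 (others 74.2 to 77.3). Csf1 stood at 22.6 CPM in G793A control replicate 3 (others 20.5 to 20.7).

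The effect of each inhibitor differed between the genotypes by the interaction test. For PLX3397 90 genes passed, with 1.88 for Csf1r, 2.26 for P2ry12, 1.97 for Tmem119, 1.89 for Cx3cr1, 1.93 for C1qa and 3.39 for Mrc1. For PLX5622 131 genes passed, with 2.75 for Csf1r, 3.32 for P2ry12, 2.37 for Tmem119, 2.98 for Cx3cr1, 2.58 for C1qa and 4.00 for Mrc1.

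Other splits of the same libraries into groups of the same sizes were counted, the real split included. For WT mice on PLX3397 against WT controls 1 of 35 splits gave as many genes (real 247, highest other 132). For PLX5622 it was also 1 of 35 (real 269, highest other 163). This is the smallest share that 35 splits can give. It is under the 0.05 set in advance, without adjustment for the number of comparisons. For the PLX5622 interaction 2 of 100 splits gave as many (real 131, highest other 429), which is under the share of 0.05 set in advance. With the trend removed it was 1 of 100 (real 133, highest other 128). The 100 are a random draw of splits, and with a split at 429 genes the count alone does not exclude chance. For the PLX3397 interaction 5 of 100 gave as many (real 90, highest other 707), so chance is not excluded by that count, while with the trend removed 2 of 100 did (real 90, highest other 159). Chance is not excluded for G793A mice on PLX3397, with 5 of 35 against WT controls (real 1, highest other 2) and 4 of 35 against G793A controls (real 1, highest other 164), or for G793A mice on PLX5622 against those on PLX3397, with 4 of 35 (real 1, highest other 2). Where the real count is 0 each split gives as many (35 of 35), so the count of splits says nothing about chance. This holds for G793A controls against WT controls (highest other 1091), WT PLX5622 against WT PLX3397 (highest other 2), and G793A mice on PLX5622 against WT controls (highest other 1) and against G793A controls (highest other 472). Splits that call several times the real count point to a structure of the samples other than the groups compared. The split with 1091 genes sets WT control replicate 1 with G793A control replicates 1, 3 and 4, which are the control libraries with a negative correlation with transcript length, and the splits with 164 and 472 genes set the same 3 G793A controls with 1 inhibitor library.

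Pdgfra was lower with PLX3397 in G793A mice, and in WT mice it did not pass (−0.30, adjusted p = 0.0716). Over all genes 1 of 12 oligodendrocyte precursor genes passed in each genotype, Pdgfra in G793A mice and Matn4 in WT mice, each against controls of the same genotype. The list did not pass with an estimated correlation (adjusted p = 0.182 in G793A mice and 0.0843 in WT mice). The committed precursor list passed in WT mice on PLX3397 (adjusted p = 0.0197 with an estimated correlation), and its score, −0.23 there, was −0.16 in WT mice on PLX5622, −0.09 in G793A controls, and −0.23 and −0.12 in G793A mice on PLX3397 and PLX5622, so what follows concerns Pdgfra and not that list. The Pdgfra call against G793A controls was lost without G793A control replicate 4 (adjusted p = 0.0535), that between the inhibitors in G793A mice without G793A PLX5622 replicate 3 (0.0833) or replicate 4 (0.0856), and that of Matn4 without any 1 of the 7 libraries but WT PLX3397 replicate 1 (highest adjusted p 0.196, without WT control replicate 1). A loss of microglia as the cause of lower Pdgfra is argued against by WT mice on PLX5622, where Pdgfra was at 0.02 against WT controls. In G793A mice Pdgfra was 0.53 ± 0.08 higher with PLX5622 than with PLX3397 (adjusted p = 0.00899), which goes the same way. That comparison reuses the G793A PLX3397 libraries in which Pdgfra was seen to be low, so it adds little. With only the groups compared in the fit, it and the comparison with G793A controls each called 0 genes. The length and GC trend is argued against, since with the trend removed Pdgfra was at −0.56 ± 0.08 (adjusted p = 0.00514) against G793A controls, where it had been at −0.54. Less white matter in the tissue is argued against by the myelinating oligodendrocyte list, whose edgeR median was 0.10 (quartiles −0.04 and 0.15) against −0.17 for the precursor list. An action of PLX3397 on precursor cells stays open as a hypothesis found and tested on the same data, as do effects of dose, since the compounds were given at 290 and 1200 mg/kg.

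Microglial genes were lower in G793A mice given either inhibitor than in G793A controls, with a difference in score of −0.25. No gene of the list passed in either comparison, and the list did not pass with an estimated correlation (adjusted p = 0.414 with PLX3397 and 0.848 with PLX5622). Without G793A PLX5622 replicate 2, which held cerebellar transcripts and 58.8 CPM of Csf1r, the median with PLX5622 went from −0.24 to −0.15. Of the 495 splits of the 12 libraries into 8 and 4, 3 gave a difference in score as large (highest other 0.28), but the inhibitor groups were pooled after both were seen to be lower, so this leaves chance open. The planned comparisons of the score had an exact permutation p of 0.0571 for each inhibitor, and both used the same G793A controls. Leaving out each of the 12 libraries in turn, the difference in score lay between −0.31 and −0.17, and the highest share was 7 of 165, without G793A control replicate 3. The length and GC trend is argued against, since the pooled edgeR median of the list was −0.24 and with the trend removed −0.25. A partial loss of microglial RNA as in WT mice could not be decided. The slope of the G793A changes on the WT changes was 0.11, and 2 of 70 splits, the real one included, gave a slope as high. The highest other was at 0.12, so the slope lay within the range of the other splits. The prediction set in advance counted that against this explanation. It is read here as undecided, because the highest other was too close to exclude or favour it. Altered expression in each cell stays open and was not tested.

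Without G793A control replicate 2, edgeR called 375 genes in G793A controls against WT controls and 980 in G793A mice on PLX5622 against G793A controls. With the length and GC trend also removed the counts were 0 and 2, which met the prediction for a length trend, but the rule for reading it was made stricter after the values were seen, because the folds mostly stayed. The median fold in the called direction went from 0.33 (median SE 0.079) to 0.24 (0.068) and from 0.29 (0.072) to 0.20 (0.064), so 72.6% and 68.4% were kept. Folds shrank more than their SEs, and the smallest adjusted p was 0.0634 and 0.0325. Of the called genes, 346 of 375 and 800 of 980 stayed at an unadjusted p under 0.05. Over all genes such p-values went from 2984 to 2273 and from 3633 to 2776, so the adjustment over all genes also bears on the lost calls. How much is length trend and how much something else cannot be told apart, since removing the trend would also remove biology that follows transcript length. A genotype effect hidden by that library is argued against, since the 375 genes had a median of 0.059 in G793A mice on PLX5622 and 0.09 in those on PLX3397 against WT controls, in the called direction, where they had 0.33, although this uses inhibitor-treated mice and the same WT controls.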

How the results depend on the processing

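Across alternatives and left-out libraries 181 gene counts stayed within 1.5 times the reported count, or at 0, and 41 moved. By their side of the threshold, 116 microglia medians stayed while 5 weakened and 3 strengthened. Where these medians were taken from edgeR fold changes the reported adjusted p was carried over, so they could not weaken or strengthen. Of genes chosen by the naming rule 2800 values stayed, 194 weakened and 54 strengthened. These include genes that did not pass as reported, such as Csf1 and Il34. No value past the threshold, as reported or under the alternative, changed direction. Of values past it in neither, 47 of genes chosen by the naming rule and 3 microglia medians changed sign. The cause was not tested unless stated. For G793A PLX3397 against WT controls, where edgeR called 1, RLE scaling called 2, no filter 2, a mean CPM of at least 1 2, DESeq2 26, limma-voom 3, the replicate block 0 (Pdgfra −0.53, adjusted p = 0.0664), only the groups compared 0 and the authors' variance-stabilised values 2. For G793A PLX5622 against WT controls (0) DESeq2 called 8, limma-voom 1, only the groups compared 3 and variance-stabilised values 1. For G793A PLX3397 against G793A controls (1) DESeq2 called 28, only the groups compared 0 and variance-stabilised values 0. For G793A PLX5622 DESeq2 called 313 against G793A controls (0) and 2 against G793A PLX3397 (1), where only the groups compared gave 0. For WT PLX5622 against WT PLX3397 (0) no filter called 1, DESeq2 14, the length and GC trend removed 1, leaving out the 2 cerebellar libraries 6 and leaving out the 4 with high Npas4 1. The PLX3397 interaction (90) had 58 with variance-stabilised values and 55 without the 4 libraries with high Npas4, where fewer samples were tested. Values of list tests past the threshold went from 109 to 15 with an estimated correlation and 26 in fry. With an estimated correlation the microglia call weakened at medians of −0.35 (G793A PLX3397 against WT controls, adjusted p = 0.134), −0.40 (G793A PLX5622, 0.169), −0.21 and −0.24 (each against G793A controls, 0.414 and 0.848) and −0.80 (WT inhibitors, 0.0804). Variance-stabilised values, the trend and the left-out sets of libraries were chosen after seeing the data. A sex covariate was not run.

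Leaving out each library in turn, counts ranged from 0 to 375 (G793A against WT controls), 181 to 216 and 220 to 278 (WT PLX3397 and PLX5622), 0 to 4 and 0 to 1 (G793A PLX3397 and PLX5622 against WT controls), 0 to 23 and 0 to 980 (the same against G793A controls), 0 to 7 (WT inhibitors), 0 to 1 (G793A inhibitors), and 68 to 93 and 115 to 144 (interactions). Microglia medians ranged from −0.23 to −0.088 in G793A controls, where leaving out WT control replicate 3 (−0.20), G793A control replicate 3 (−0.23) or replicate 4 (−0.16) put the list past the threshold with the preset correlation (adjusted p = 0.994 with an estimated correlation and all libraries). They ranged from −2.28 to −2.00 and −3.24 to −2.88 (WT PLX3397 and PLX5622), −0.42 to −0.32 and −0.45 to −0.34 (G793A on them against WT controls), −0.27 to −0.14 and −0.28 to −0.15 (against G793A controls), −0.998 to −0.60 (WT inhibitors) and −0.09 to 0.03 (G793A inhibitors, −0.06 with all libraries and 0.03 without G793A PLX5622 replicate 2). At 26.3 M counts or more per library, depth limits genes of few counts, such as Cd209f (0.487 CPM in WT controls, SE 0.99 for the PLX5622 interaction).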

Other observations

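With PLX3397 and PLX5622 in WT mice the astrocyte list had medians of 0.01 and −0.01, pan-neuronal genes 0.04 and 0.04, excitatory neurons 0.17 and 0.09, inhibitory neurons 0.04 and 0.13, synapse genes 0.12 and 0.08, endothelial genes −0.11 and −0.15, mural cell genes −0.08 and −0.08, and myelinating oligodendrocyte genes −0.03 and −0.07. In each of these lists 0 genes passed over all genes in edgeR, and none of the lists passed with an estimated correlation. With the preset correlation excitatory neurons (adjusted p = 0.00975) and synapse genes (0.00198) passed with PLX3397, and endothelial genes with PLX3397 (0.00731) and PLX5622 (0.0138). With an estimated correlation these were 0.388, 0.388, 0.397 and 0.591. Scores did not overlap with those of WT controls for endothelial genes with PLX3397 (difference −0.12, exact permutation p = 0.0571) and inhibitory neurons with PLX5622 (0.12, exact permutation p = 0.0286). Blood leukocyte genes had medians of 0.71 with PLX3397 and 1.21 with PLX5622 in WT mice, 0.67 in G793A controls, and 0.84 and 1.65 in G793A mice on the inhibitors, each against WT controls, and none passed with an estimated correlation. Without G793A control replicate 2, 29 of 78 ribosomal protein genes were higher in G793A controls than in WT controls (median 0.33, and 0.24 with the length and GC trend removed), and 42 were lower in G793A mice on PLX5622 than in G793A controls (median −0.30, and −0.20 with the trend removed). Of 47 complex I subunit genes 17 were higher (median 0.28, then 0.19) and 21 lower (median −0.22, then −0.15). With the trend removed 0 genes of either family passed in either comparison, and neither family was tested as a group.

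The tests in this part were fixed before their values were seen, except that the readings of both were made stricter afterwards. The 12 genes that rose with PLX5622 in WT mice might have done so through low values by chance in the 3 WT controls. Against G793A controls, with WT PLX5622 libraries unchanged, their median was 0.24 where it had been 0.41, and 0 of 12 were negative. This met the bound set in advance against that explanation, but by less than the spread of the genes (lower quartile 0.13). The same 12 genes had a median of 0.22 in G793A controls against WT controls, where no inhibitor was given, with 0 negative. In G793A mice on PLX3397 and PLX5622 they had medians of 0.34 and 0.32 against WT controls and of 0.03 and 0.12 against G793A controls. Low WT control values could therefore account for part of the rise, and the test leaves open how much. Dbp and Usp2, which rose with PLX3397 in WT mice, follow the daily clock, and another time of day for tissue collection is a candidate explanation. The 11 clock genes with evening peaks had a median of 0.19 and the 5 with morning peaks −0.01 (median SE 0.0978). With the separation of scores given below, this met the prediction set in advance for that explanation. The opposite sign that the explanation needs was within error, however, and the stricter reading asks for more. Among evening genes Ciart was at 0.76 (adjusted p = 0.0805), Per1 at 0.51, Nr1d1 at 0.40, Per3 at 0.06, Tef at 0.05 and Per2 at 0.03, and among morning genes Arntl was at −0.12, Cry1 at −0.11, Npas2 at 0.09 and Nfil3 at 0.20. The lowest evening minus morning score of a WT PLX3397 library lay 0.13 above the highest WT control score. In G793A mice on PLX3397 3 of 4 libraries (0.13, 0.31 and 0.36, the other −0.02) lay above each of the 7 control libraries, whose highest was 0.07, with Ciart at 0.78 and Per1 at 0.70 against G793A controls (adjusted p = 0.287 and 0.333). With PLX5622 scores lay between −0.01 and 0.12 in WT mice and between −0.03 and 0.13 in G793A mice. A shift with the PLX3397 diet and another time of day for those groups would both look like this, and the test leaves the explanation undecided.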
